A study of Mus musculus with 4 samples.

How the data were processed

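RNA of the globus pallidus of 4 cocaine mice and 4 saline mice was measured on 4 Agilent whole mouse genome arrays with 2 colours. Per the labels, total RNA was purified with a PicoPure kit, labelled by linear amplification with Cy3 or Cy5, and hybridised with dyes exchanged between arrays. Every channel carries its own animal's code, so each array is 1 pair of mice and all 4 are biological replicates of the single comparison the design holds. Pairs are numbered 1 to 4. The submitters' processing notes name Agilent Feature Extraction; its version, background correction and normalization are not given in the sources used here.

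The deposited table holds 1 log2 ratio per feature and array, 45220 features with 0 missing values. What the authors did to these ratios was read from the values. On arrays 1 and 3, which keep 16 digits, 2 to the power of the value is a ratio of 2 whole numbers for 99.38% and 99.42% of values, against 14.6% and 14.66% for base 10. The values are therefore read as log2 ratios of scanner signals without background subtraction or dye normalization. The medians of the columns were 0.42, -0.58, 0.41 and -0.43 on arrays 1 to 4. Groups of unlisted features were picked by their mean ratio after turning by dye orientation. Their change of sign with the dye (medians of 4.57, -4.80, 4.88 and -4.83 for the group with the highest values) follows from that choice. Without such a choice, the ratios of all features correlated at 0.892 and 0.889 within a dye orientation and at -0.847 to -0.947 between orientations. The columns are therefore read as turned to 1 treatment direction. Which treatment is the numerator stays unstated. Because background remains in the ratios, changes of dim genes are understated. Scanner files were not used here, so background correction by intensity, saturation and slide batches were not tested.

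The design fixed before the data were examined assumed normalized ratios. As the table holds unnormalized ones, loess within each array was added before any gene was tested, and the ratios as deposited became an alternative. For loess, the mean signal of both channels was recovered from the reduced fractions of arrays 1 and 3, with a common multiple of at most 40 chosen so that the mean signals of both arrays agree, above a floor of 90. This gave a signal for 43915 features (97.1%), with a correlation of 0.995 between the 2 arrays and a median of 185 scanner units. Tested on simulated data (5000 features), 97.9% were resolved and 91.7% lay within 0.25 log2 of the truth. The same signal served for arrays 2 and 4, whose values have about 7 digits. Loess was fitted on features listed with a gene (limma loessFit, span 0.3, 4 iterations).

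Features were named from the platform annotation: 33653 had 1 symbol, 56 several and 11511 were not listed and stay unnamed here. Of the listed features, 33517 matched an Entrez ID in the RefSeq gene table (assembly GRCm38.p6, used for names only), and 0 symbols needed updating. Features of 1 symbol were averaged (8118 genes have several), including different probes of a gene; the features of Tcf7l2, En2, Gabra3, Sox9, Cx3cr1, Per2, Penk, Tac1, Gfap and Mbp disagreed in sign. Features at 0 on all arrays numbered 202.

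The ratios of 18818 genes were fitted with limma (lmFit, eBayes, two-sided, Benjamini-Hochberg) on Cy5 over Cy3, with a dye term and a cocaine coefficient of opposite sign in the 2 orientations, which leaves 2 residual degrees of freedom and a prior of 4.07. The SE of a gene is the moderated standard error of this coefficient. A gene's dye effect does not widen it, so pairs of opposite orientation can lie further apart than it shows. The 31 gene lists, fixed before the data were examined, were tested with camera (preset correlation 0.01), with an estimated correlation (also in every alternative; this test rests on 2 residual degrees of freedom, or 1 without a pair, so it has little power) and with fry, and each median was set against 10000 random lists matched on signal. Tested on simulated data for this comparison (18818 genes, 200 changed), 97% of changes of 0.5 log2 and 100% of changes of 1 passed the adjusted threshold, as did 18 unchanged genes. The simulated noise was independent between genes. It put 204 unchanged genes at an unadjusted p under 0.01 in limma, where the real fit had 45 genes in all. The simulation therefore checks the code and does not show that changes of this size would be found in these data.

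Named genes followed a rule fixed before the data were examined. It takes up to 12 genes per direction with the same sign on all 4 arrays, by change among those past the threshold and otherwise by unadjusted p among those with an absolute log2 change of at least 0.5. It adds, from each list, up to 4 members past the threshold or otherwise the 2 with the smallest unadjusted p, and the references Fos, Egr1, Arc, Drd1, Drd2, Penk, Tac1, Pvalb, Gad1, Ttr, Gfap and Mbp. RIKEN, Gm and LOC symbols are counted but not named by it. Genes named for their position or for calls without 1 pair, and the interferon genes beyond Gbp3 and Rsad2, were chosen after their values were seen.

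Alternatives changed the dye term, the reading of the columns, centring, scaling, quantile normalization, averaging of features, 2 filters, the variance model, array weights, the loess span, the list test and the pairs included. Values given without 1 pair are fitted changes with the dye term, not averages of the remaining pairs. The pair left alone in its dye orientation then weighs as much as the other 2 together and adds nothing to the estimated spread. Local defects were sought from the feature numbers, taken as 532 rows of 85 features; normalized ratios 1 row apart correlated at 0.013 to 0.026 on the 4 arrays, against medians of 0.0020 to 0.0069 over 300 distances. A feature was placed in a patch where the median of its up to 24 neighbours was beyond 0.25 (231 features). R 4.3.3, limma 3.58.1, the data.table package (version 1.17.8), Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.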

Results

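RNA levels were compared in the globus pallidus, a basal ganglia nucleus that receives dense GABA input from the striatum and sends inhibitory output, between mice given cocaine and mice given saline. The animals were male C57BL6 mice put through conditioned place preference, a test in which an animal learns to prefer the compartment where it received a drug. Cocaine was given at 15 mg/kg on days 2, 3 and 4 of that protocol, and the cocaine mice had a high preference score. Each of 4 Agilent whole-genome mouse arrays carried RNA of 1 cocaine mouse and 1 saline mouse in its 2 dye channels, so that 4 mouse pairs (8 channels, 4 mice per treatment) were measured. Cocaine RNA was labelled with Cy5 in pairs 1 and 3 and with Cy3 in pairs 2 and 4. The number of arrays limits the precision of every value below.

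Log2 changes are given as cocaine over saline. The columns are read as turned to 1 direction of treatment, because the ratios of all features reversed with the dye orientation. Which treatment is the numerator is not stated. Cocaine over saline is the likely direction, because the design names the cocaine mice first and sets them against the saline mice.

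No single gene differed between cocaine and saline past the threshold. The main fit used all 4 pairs, with the loess and dye term described above. In it, the interferon response was the only one of 31 gene lists past the threshold. Other lists also passed with all 4 pairs when the normalization, the loess span, the dye term or the averaging of features was changed. The interferon call was lost with an estimated correlation (adjusted p = 0.937) and with fry (adjusted p = 0.962). Avp and Amd2 had the largest positive and Plac9a the largest negative log2 changes among genes with the same direction in all 4 pairs, without passing the threshold. Of 18818 genes tested with limma, 0 were higher and 0 lower at an adjusted p under 0.05, and the smallest adjusted p was 0.971. At an unadjusted p under 0.05 there were 481 genes, and at an unadjusted p under 0.01 there were 9 higher and 36 lower, 45 in all, where chance gives 188. The same direction in all 4 pairs was seen for 1101 genes (5.9%), where 4 independent signs give 12.5%. The signs were not independent: normalized ratios of pairs of opposite dye orientation correlated at -0.389 to -0.685. The dye effect left in the ratios thus makes a shared direction rarer, so this share says nothing on the treatment. The median absolute log2 change was 0.050 and the median standard error 0.066. With the arrays scaled to the same spread, 17 genes were higher and 39 lower at an unadjusted p under 0.01. These counts moved with single pairs, and of the 76 genes named by rule, 54 moved by over 1.5 times without 1 pair, 12 of them across 0. A fit without 1 pair leaves a single array in 1 dye orientation, so calls made there lean on that array. Without pair 1, 2, 3 or 4, the number higher was 41, 11, 119 and 144, and the number lower 6, 78, 47 and 602. At an adjusted p under 0.05, 3 genes were lower without pair 2, and 1 was higher and 2 were lower without pair 4.

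Among genes with the same direction in all 4 pairs and an absolute log2 change of at least 0.5, Avp and Amd2 were the highest in cocaine and Plac9a the lowest, none past the threshold; if the ratios are saline over cocaine, this order is turned. Avp, the vasopressin precursor, had a log2 change of 0.66 ± 0.18 (moderated SE after the dye term, n = 4), with 0.83, 1.29, 0.30 and 0.24 in pairs 1 to 4. Its signal was dim, at 192, and its change was 0.40 without pair 2. Amd2, an adenosylmethionine decarboxylase of polyamine synthesis, had 0.59 ± 0.20, with 1.15, 0.98, 0.20 and 0.046 in the 4 pairs, and 0.36 without pair 1 or without pair 2. Plac9a had -0.61 ± 0.074, with -0.93, -0.50, -0.83 and -0.17 in the 4 pairs. It had the smallest unadjusted p of all genes and an adjusted p of 0.971. Tmem259 stood at -0.52 ± 0.092 and Zswim2 at -0.52 ± 0.20 (-0.85 without pair 2 and -0.19 without pair 4). Both lay in a patch of the pair 4 array where the surrounding features were shifted down too, with local medians of -0.58 and -0.66.

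The interferon response list was the only one of 31 gene lists past the threshold in this fit, with 17 of its 19 measured genes above 0, a mean log2 change of 0.12 and a median of 0.11 (camera in limma, adjusted p = 9.5e-05). The call was lost with an estimated correlation (camera adjusted p = 0.937) and with fry (adjusted p = 0.962). The estimated correlation rests on 2 residual degrees of freedom and has little power, so a loss with it says little against a list. For the interferon list it was 0.41, against the preset of 0.01. If its members are correlated to that degree, the p-value of the preset is far too small, so the call is weak. No member passed on its own, whether adjusted over all genes or adjusted over the list alone. Gbp3, an interferon-induced GTPase, had 0.37 ± 0.11 (moderated SE after the dye term, n = 4) and 0.21 without pair 3. Its ratios were 0.90, -0.38, 1.52 and -0.57 in pairs 1 to 4. Rsad2, an antiviral enzyme, had 0.25 ± 0.080 (0.15 without pair 3), with ratios of 0.38, -0.064, 0.78 and -0.10. The list did not move one way in the 4 pairs. Its mean was 0.35 in pair 1, -0.31 in pair 2, 0.72 in pair 3 and -0.30 in pair 4, so that it was higher in whichever mouse was labelled with Cy5, or with Cy3 if the ratios are saline over cocaine. Without pair 3 the mean fitted change (with the dye term) was 0.024 (camera adjusted p = 0.614), and without pair 1 it was 0.21. With the ratios as deposited it was 0.015 against a median of -0.085 over all genes, and the list still passed (adjusted p = 9.5e-05). Microglia and macrophage markers also differed between pairs, at 0.065, -0.32, 0.30 and -0.023.

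**Figure D1:**
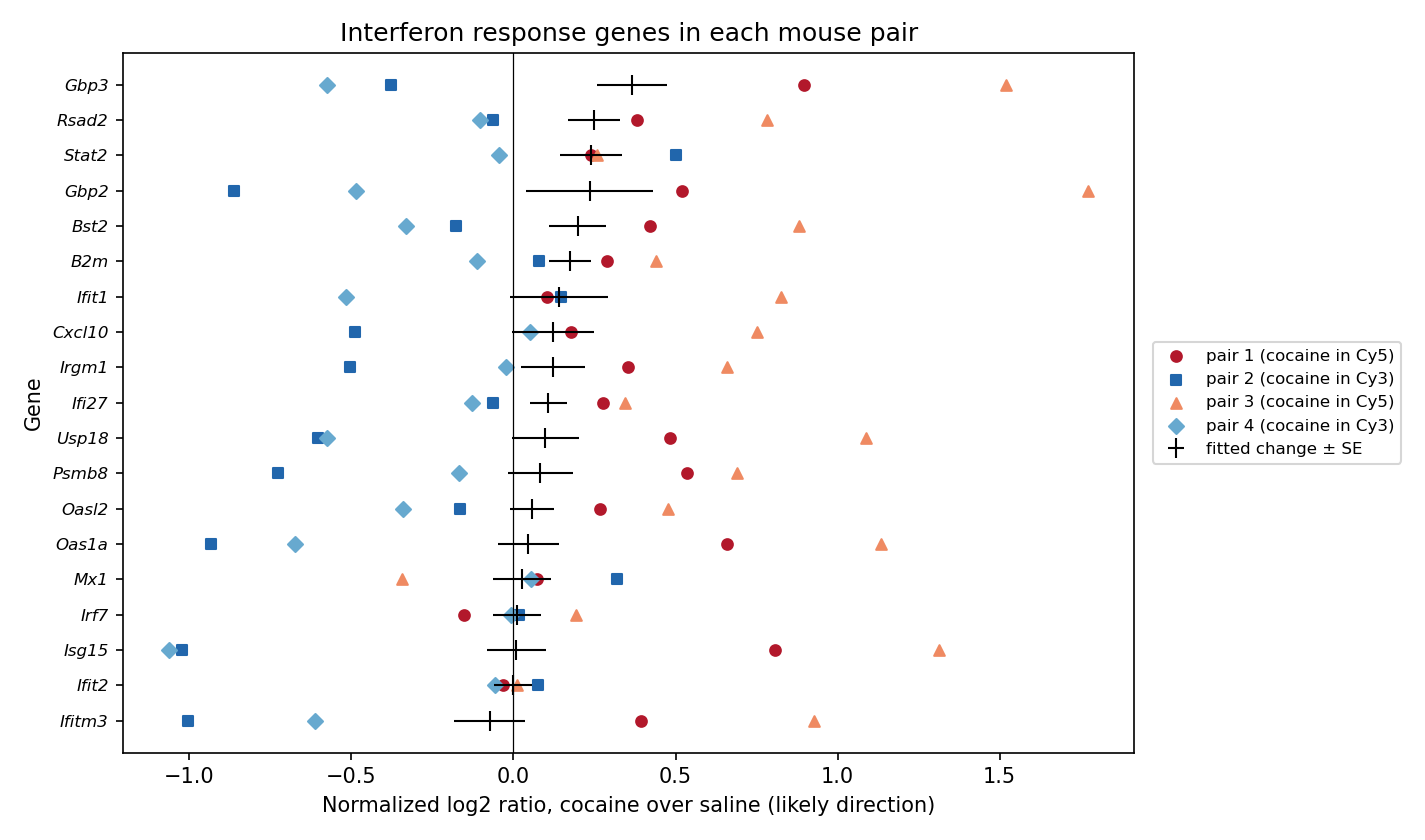
Normalized log2 ratio (cocaine over saline, the likely direction) of the 19 measured interferon response genes; coloured points are the 4 mouse pairs, and the black mark with its bar is the fitted change ± SE. For Isg15 the points of pairs 1 and 3, with cocaine in Cy5, lie at 0.81 and 1.31, and those of pairs 2 and 4 at -1.02 and -1.06.

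In the main fit, no gene in any of the 31 lists passed, adjusted over all genes or adjusted over the list alone, and the 30 other lists stayed short of the threshold. Without pair 4, Pdyn, a member of the striatal and of the dopamine and opioid lists, passed (1.08, adjusted p = 0.0327 over all genes in limma). It had 0.29 with all 4 pairs. Without pair 4, pair 2 is the only array of its dye orientation, so the 1.08 leans on it and the spread comes from pairs 1 and 3. Immediate early and activity-regulated genes had 19 of 30 members above 0 and a mean of 0.034 (adjusted p = 0.170). Dusp1, a phosphatase that switches off MAP kinases, had 0.15 ± 0.063 and was above 0 in all 4 pairs, and Ier5 had 0.28 ± 0.12 (0.094 without pair 1 and 0.46 without pair 3). The classical activity markers Fos, Egr1 and Arc had 0.056 ± 0.072, 0.067 ± 0.18 and -0.0099 ± 0.061. Chromatin regulators studied in cocaine reward had 15 of 22 members above 0 (mean 0.024, adjusted p = 0.264), with Baz1b at 0.19 ± 0.11 (0.038 without pair 1 and 0.34 without pair 3) and Hdac4 at 0.13 ± 0.091 (0.038 without pair 2 and 0.22 without pair 4).

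Among neuronal lists, cholinergic neuron markers had the lowest mean, -0.11, with 8 of 10 members below 0 (adjusted p = 0.0944). Ache, which breaks down acetylcholine, had -0.19 ± 0.058, with ratios of -0.55, 0.087, -0.49 and 0.21 in pairs 1 to 4. Ecel1 had -0.20 ± 0.084 (-0.28 without pair 1 and -0.12 without pair 3). The list mean was 0.14, 0.089, -0.20 and -0.46 in pairs 1 to 4. The mean fitted change of the list was -0.19 without pair 1 (camera adjusted p = 1.1e-04), -0.24 without pair 2 (camera adjusted p = 3.0e-08), -0.023 without pair 3 and 0.028 without pair 4. Both calls were lost with an estimated correlation (adjusted p = 0.990 without pair 1 and adjusted p = 0.748 without pair 2). Striatal projection neuron markers had 14 of 22 members below 0 (mean -0.033, camera adjusted p = 0.189). Adcy5, the main striatal adenylyl cyclase, was at -0.21 ± 0.079 (-0.13 without pair 1 and -0.29 without pair 3) and Rasd2 at -0.12 ± 0.061. The striatal references Drd1, Drd2, Penk and Tac1 had 0.015 ± 0.22, -0.14 ± 0.085, 0.0064 ± 0.091 and 0.022 ± 0.072. The mean of the striatal list was 0.20 in pair 2 and -0.26 in pair 4. Its mean fitted change was -0.15 without pair 2 (camera adjusted p = 1.4e-12, or adjusted p = 0.748 with an estimated correlation) and 0.082 without pair 4 (camera adjusted p = 0.0955). Pallidal neuron markers were centred near 0 (mean -0.019, camera adjusted p = 0.835), with Npas1 at -0.10 ± 0.055, Kcng4 at -0.15 ± 0.073, Pvalb at 0.061 ± 0.072 and Gad1 at 0.095 ± 0.059. Kcng4 was at -0.075 without pair 2 and -0.23 without pair 4, and Pvalb at -0.020 without pair 1. In the same fit, markers of neighbouring regions also stayed short of the threshold: cortical glutamatergic neurons (mean -0.021, adjusted p = 0.823), thalamic neurons (-0.030, 0.727), midbrain dopamine neurons (-0.018, 0.823) and hypothalamic neuropeptides (0.011, 0.711). Without pair 2 the thalamic list was at -0.076 (camera adjusted p = 0.0082) and the neuropeptides at -0.058 (camera adjusted p = 0.0148), both lost with an estimated correlation (adjusted p = 0.748). Without pair 4 they were above 0, at 0.016 and 0.080. Emx1 had -0.27 ± 0.11 (-0.10 without pair 2 and -0.43 without pair 4), Slc17a6 -0.17 ± 0.065 and Th -0.073 ± 0.071. Within the neuropeptides, Gal, the galanin precursor, had -0.30 ± 0.084, opposite in sign to Avp.

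**Figure D2:**
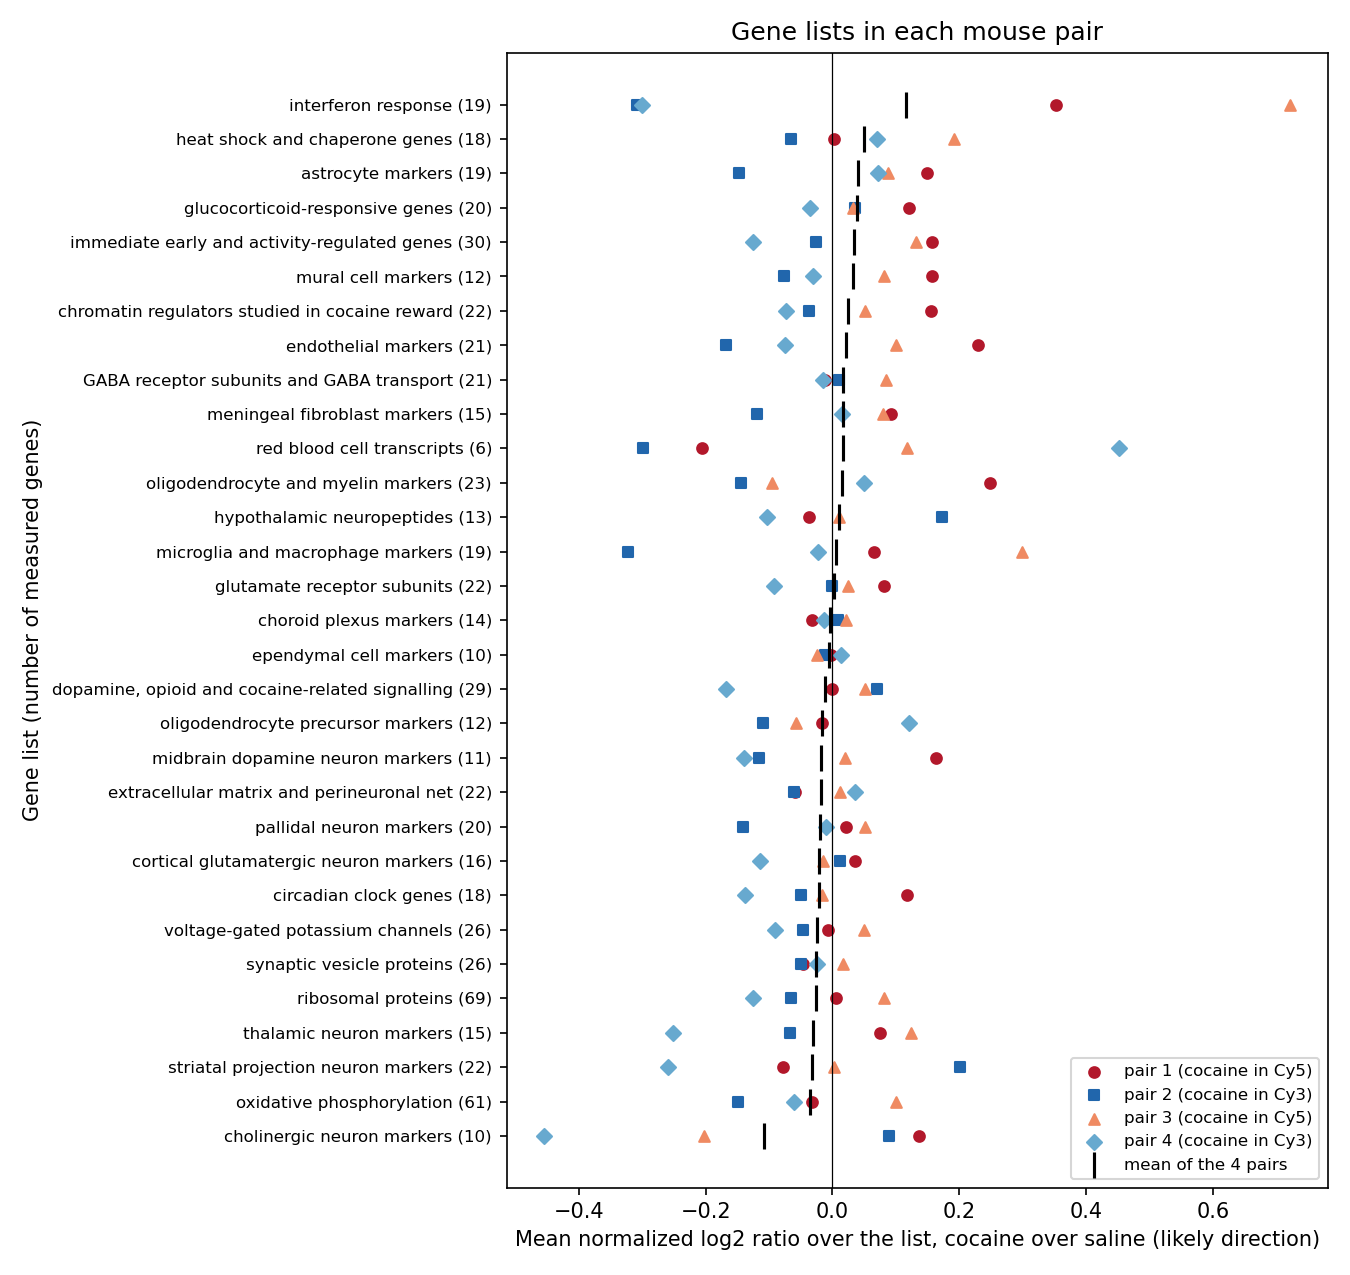
Mean normalized log2 ratio (cocaine over saline, the likely direction) of each gene list, with the number of measured genes in brackets; coloured points are the 4 mouse pairs and the black bar is their mean. The interferon list spans -0.31 to 0.72 and the red blood cell list -0.30 to 0.45, while no list mean is beyond 0.12 in either direction.

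Dopamine, opioid and cocaine-related signalling had 13 of 29 members above 0 (mean -0.012, adjusted p = 0.727), with Cdk5, a kinase that regulates dopamine signalling, at -0.19 ± 0.066. Without pair 2 that list was at -0.072 (camera adjusted p = 6.3e-04, or adjusted p = 0.748 with an estimated correlation), and without pair 4 at 0.047. GABA receptor subunits and GABA transport had a mean of 0.017 (adjusted p = 0.727). Gabra4, a GABA-A receptor subunit, had 0.50 ± 0.18, from 0.93 in pair 1 to -0.16 in pair 4, and 0.23 without pair 2 and 0.76 without pair 4. Glutamate receptor subunits had a mean of 0.0032 (adjusted p = 0.745), with Grm5, a metabotropic receptor, at 0.20 ± 0.081 (0.12 without pair 1) and Grin3a at -0.20 ± 0.10 (-0.34 without pair 2 and -0.065 without pair 4). Voltage-gated potassium channels had a mean of -0.024 (adjusted p = 0.967), with Kcnc4 at -0.32 ± 0.11 (-0.21 without pair 1 and -0.20 without pair 2), a feature that lay in a patch of shifted neighbours. Synaptic vesicle proteins had 18 of 26 members below 0 (mean -0.026, adjusted p = 0.711), with Rab3b, a vesicle GTPase, at -0.17 ± 0.061 and below 0 in all 4 pairs.

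Astrocyte markers had 13 of 19 members above 0 (mean 0.040, adjusted p = 0.104), with Sox9 at 0.16 ± 0.073 (0.082 without pair 1 and 0.24 without pair 3), Fabp7 at 0.12 ± 0.058 and Gfap at -0.042 ± 0.074 (0.040 without pair 2 and -0.12 without pair 4). The astrocyte list was at 0.095 without pair 2 (adjusted p = 1.8e-04, or adjusted p = 0.748 with an estimated correlation) and at -0.015 without pair 4. Trf, of the oligodendrocyte and myelin markers, had -0.18 ± 0.076 (-0.096 without pair 2 and -0.27 without pair 4). Mbp had -0.082 ± 0.088 (-0.18 without pair 1 and 0.019 without pair 3). The oligodendrocyte and myelin list had a mean of 0.015 (camera adjusted p = 0.748). Without pair 1 that list was at -0.071 (adjusted p = 0.0071) and without pair 3 at 0.10 (adjusted p = 0.0097). Both calls were lost with an estimated correlation (adjusted p = 0.990 and adjusted p = 0.985). Oligodendrocyte precursors were at -0.016 (adjusted p = 0.816), microglia and macrophages at 0.0046 (0.584), endothelium at 0.022 (0.493), mural cells at 0.033 (0.612), meningeal fibroblasts at 0.017 (0.584), choroid plexus at -0.0040 (0.894), ependyma at -0.0060 (0.955) and red blood cell transcripts at 0.016 (0.727). The microglia list was at 0.063 without pair 1 (adjusted p = 0.0026), 0.080 without pair 2 (adjusted p = 2.4e-04), -0.054 without pair 3 and -0.070 without pair 4. Its calls were lost with an estimated correlation (adjusted p = 0.990 without pair 1 and adjusted p = 0.748 without pair 2). Red blood cell transcripts were at 0.20 without pair 2 (camera adjusted p = 1.5e-04, or adjusted p = 0.748 with an estimated correlation), -0.065 without pair 3 and -0.17 without pair 4. Cx3cr1, a microglial receptor, had 0.091 ± 0.056. Rgs5, a pericyte gene, had 0.32 ± 0.14, with 0.85, 0.19, -0.058 and 0.32 in the 4 pairs, and 0.097 without pair 1 and 0.55 without pair 3.

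Heat shock and chaperone genes had 13 of 18 members above 0 and a mean of 0.050 (adjusted p = 0.0857). Its leading members were chaperones of the endoplasmic reticulum, Hspa5 at 0.16 ± 0.060 and Hsp90b1 at 0.26 ± 0.10 (0.11 without pair 2 and 0.41 without pair 4). The mean fitted change of the list was 0.097 without pair 1 (camera adjusted p = 9.5e-06), 0.084 without pair 2 (camera adjusted p = 1.9e-04), 0.0028 without pair 3 and 0.016 without pair 4. Both calls were lost with an estimated correlation (adjusted p = 0.990 without pair 1 and adjusted p = 0.748 without pair 2). Glucocorticoid-responsive genes had a mean of 0.038 (adjusted p = 0.170), with Plin4 at 0.31 ± 0.16 (0.052 without pair 2 and 0.57 without pair 4). Circadian clock genes were at -0.021 (adjusted p = 0.816), with Dbp at -0.21 ± 0.096 (-0.34 without pair 2 and -0.077 without pair 4) and Per2 at -0.12 ± 0.056. Oxidative phosphorylation had 42 of 61 members below 0 (mean -0.036, adjusted p = 0.198) and ribosomal proteins 41 of 69 (mean -0.026, adjusted p = 0.206). The former was at -0.069 without pair 3 (adjusted p = 0.0323) and the latter at -0.041 without pair 2 (adjusted p = 0.0014), both lost with an estimated correlation (adjusted p = 0.985 and adjusted p = 0.748). Extracellular matrix and perineuronal net genes were at -0.018 (adjusted p = 0.823). The mean and the test differed in sign for hypothalamic neuropeptides and choroid plexus, the median and the test for GABA receptor subunits, voltage-gated potassium channels, ependyma and choroid plexus.

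The dye left a larger mark than the treatment. Across genes, which are not independent replicates, the deposited ratios of 2 pairs of the same dye orientation correlated at 0.892 and 0.889, and those of opposite orientation at -0.847 to -0.947. After normalization within arrays these were 0.525 and 0.517, and -0.389 to -0.685. A dye effect at an adjusted p under 0.05 (limma) remained for 1786 genes.

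**Figure D3:**
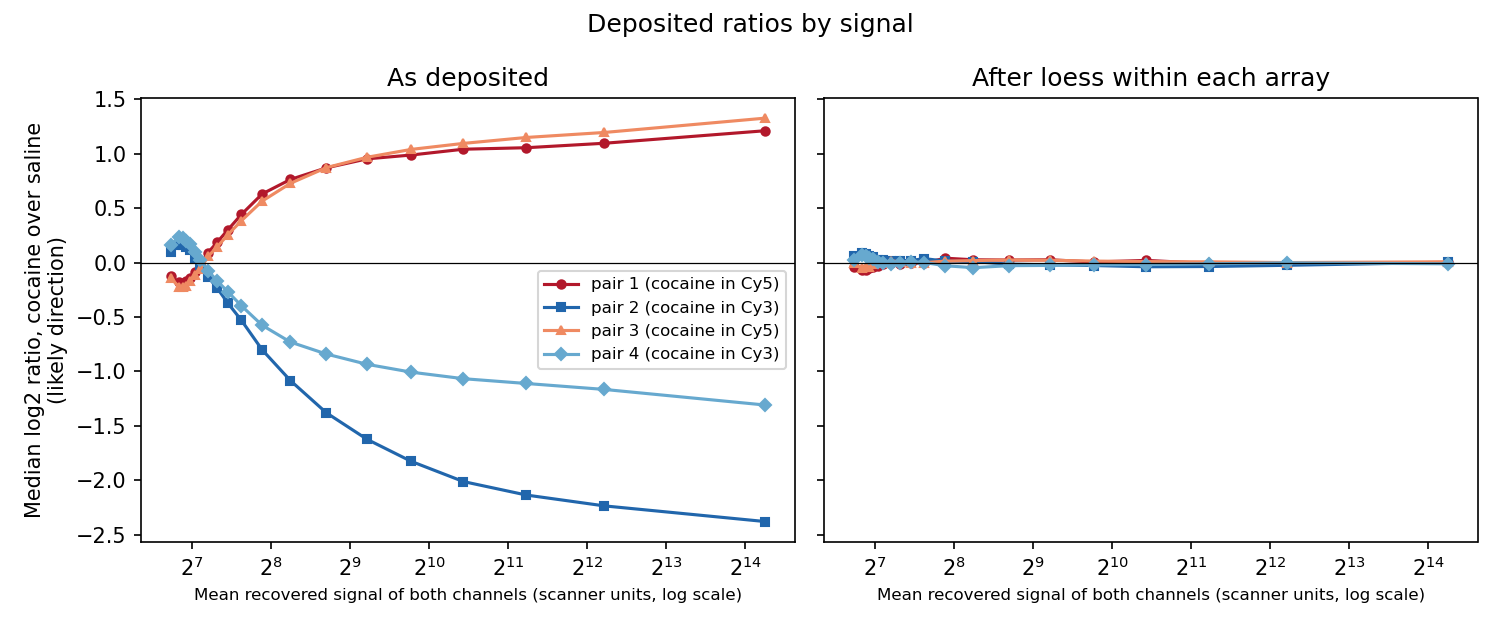
Median log2 ratio (cocaine over saline, the likely direction) of features in 20 groups of equal size by mean recovered signal (scanner units, log axis), for each of the 4 pairs, as deposited and after loess. As deposited, the brightest features had medians of 1.21 and 1.33 in pairs 1 and 3 and of -2.38 and -1.31 in pairs 2 and 4.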

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

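The tests of local defects, of microglia, of cell makeup and of the dye term were chosen after the result was seen; those of a single pair, of dim features and of other splits were set before. Among 107 series of 4 values checked (named genes and list means), 1 had a value far from the other 3, where chance alone gives about 1 in 20.

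Zswim2 had a normalized log2 ratio of -1.49 in pair 4, against -0.31 to -0.10 in the other pairs. A local defect of that array is a candidate cause. The features around it had a median of -0.66 on that array, lower than around all but 0.038% of features, and 0.13 or less in size in the other pairs. Tmem259, Olfr2 and Lrrc6 lay in the same kind of neighbourhood in pair 4, with local medians of -0.58, -0.92 and -0.49. In pair 2, D730050B12Rik and 4930482G09Rik had ratios of -5.58 and -5.67 in neighbourhoods at -0.35 and -0.36. Of these genes, Olfr2 and Lrrc6 (with 5730460C07Rik) passed without pair 2, and D730050B12Rik and 4930482G09Rik (with Pdyn, higher) without pair 4. Zswim2 and Tmem259 passed in no fit without 1 pair. A difference between the mice in Zswim2 itself stays open.

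The interferon response list was higher on average in cocaine mice, in the likely direction of the ratios. Dim features alone do not account for it: its 9 members above the signal minimum had a median of 0.17, above every random list matched on signal. A single mouse pair could: without pair 3 the mean fitted change was 0.024, against 0.12 with all 4. More microglia or macrophages cannot be told apart from it. Their list had a median of 0.013 over all pairs, within the range of random lists, but one of 0.26 in pair 3, above every random list, so they moved with the interferon genes in the pair that carries the call. A response to cocaine was not tested apart from these. Random lists leave out the correlation of genes within a list, so a median above every random list is a generous mark.

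Fewer genes passed an unadjusted p under 0.01 than chance gives (45 against 188). Whether the degrees of freedom spent on the dye term account for this stays open: the fit without that term gave 6, but it leaves the dye effect in the residual (median moderated SD 0.174, against 0.131 with the term). Cell makeup or dissection that differed between mouse pairs could: for 7 of 17 cell type lists the median differed between the 2 pairs of at least 1 orientation by more than 95% of 2000 random lists matched on signal. Each list had 2 chances to qualify, 1 per orientation, and random lists leave out the correlation of genes within a list, so this count is generous. Striatal, thalamic and endothelial markers qualified in 1 orientation only, the rest of the 7 in both. Red blood cell transcripts differed by -0.47 and -0.94, cholinergic markers by 0.28 and 0.54 and oligodendrocyte markers by 0.35 and -0.22 (pair 1 minus 3, and 2 minus 4).

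With the dye kept as a term, the 4 arrays allow 3 splits, too few for a share under 0.05. The real split gave 45 genes at an unadjusted p under 0.01 and the highest other 148; at an adjusted p under 0.05 the values were 0 and 0, and for lists 1 and 10. All 3 of the 3 splits gave as many as the real one. The number of genes that chance gives, 188, lies above all of these. The interferon list had an unadjusted camera p of 3.1e-06 (higher) in the real split. In the other splits its unadjusted camera p was 6.0e-04 and 0.0052 (lower in both). A small p of this list is therefore not particular to the split by treatment.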

How the results depend on the processing

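The ratios as deposited, the loess span of 0.7, the removal of local patches, the signal minimum and the estimated correlation within other settings were chosen after seeing the data. At an adjusted p under 0.05, 0 genes were called in either direction in every setting run, except without 1 pair (0 to 1 higher, 0 to 3 lower) and with the columns read as Cy5 over Cy3 (1621 higher, 165 lower, the dye term of the fit; 2110 and 351 at an unadjusted p under 0.01). At that unadjusted p, against 9 higher and 36 lower, the numbers were 0 and 6 without a dye term (122 at an unadjusted p under 0.05), 0 and 1 as deposited (70), and 2 and 4 with a change of at least 0.5 required. There were 17 higher after scaling, 14 and 72 after quantile normalization, 14 higher without genes near 0 on all arrays, 23 lower with every feature on its own and 17 lower above the signal minimum. Leaving out 1 pair gave 11 to 144 higher and 6 to 602 lower. Lists past the threshold, 1 in the report, numbered 2 without a dye term, 5 after scaling, 4 after quantile normalization, 8 with every feature on its own, 6 as deposited, 2 with a span of 0.7, and 0 with an estimated correlation or fry. They numbered 1 to 11 without 1 pair. With all 4 pairs, heat shock genes were called (higher) without a dye term, after scaling, after quantile normalization, per feature and with a span of 0.7. Cholinergic markers were called (lower) after scaling, after quantile normalization, per feature and as deposited; striatal markers (lower) after scaling, per feature and as deposited; astrocyte markers (higher) after scaling, after quantile normalization and per feature. Ribosomal proteins (adjusted p = 2.6e-09), oxidative phosphorylation (1.4e-07) and synaptic vesicle proteins (0.0171) were called (lower) as deposited. Per feature, endothelial (3.5e-04) and meningeal (0.0016) markers were called (higher) and ribosomal proteins (0.0303) lower. With an estimated correlation 0 lists were called in each of these settings or without any 1 pair (smallest adjusted p 0.748, in camera of limma). That test has 2 residual degrees of freedom, or 1 without a pair, so 0 calls with it says little against any list. The oligodendrocyte and myelin list changed direction without pair 1, in a range of -0.071 to 0.10. Without 1 pair, 1 dye orientation holds a single array, which the fit follows exactly, so calls made there lean on that array. Beyond this and the fewer samples or genes that a setting leaves, the cause of these shifts was not tested.

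The interferon list stayed past the threshold in every other camera setting with the preset correlation, except without pair 3 (range of adjusted p 3.8e-16 to 0.614). Across the list results and the settings tested with the preset correlation, 432 kept the direction of the test and side of the threshold, 36 passed it newly, 1 lost it, 1 passed it in the other direction and 55 changed direction without passing. For named genes these were 1226, 0, 0, 0 and 46. Other readings of single genes under Cy5 over Cy3 are the dye term and are not listed. The alternative on missing values moves nothing, as there are 0, and was not run. No separate paired analysis was run, because each array is 1 pair and its ratio already compares both mice. Of 18818 genes, 9468 were above the signal minimum.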

Other observations

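Both tests in the last paragraph were chosen after the result was seen. Some striatal genes differed strongly between mouse pairs. Pdyn, the dynorphin precursor of the direct pathway, had ratios of 0.043, 2.06, 0.15 and -1.07 in pairs 1 to 4, a fitted change of 0.29 ± 0.45. The choline transporter Slc5a7 had 0.64, 0.70, -0.41 and -0.83. Hemoglobin transcripts moved together, Hbb-bt from -0.41 in pair 1 to 0.80 in pair 4, Hba-a1 from -0.29 to 0.44. Gbp4, an interferon-induced GTPase outside the list, had 0.50 ± 0.088, with 0.91, -0.24, 1.29 and 0.055. Tmem242 had -0.48, -0.45, -0.33 and -0.32 in the 4 pairs (-0.40 ± 0.062), and Pmepa1, which dampens TGF-beta signalling, -0.49, -0.35, -0.24 and -0.33. All of these were named after their values were seen, and none passed the adjusted threshold with all 4 pairs.

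If the ratios are cocaine over saline, as is likely, interferon genes were higher on average in the mouse labelled with Cy5 in all 4 pairs; if they are saline over cocaine, in the mouse labelled with Cy3, with every dye effect of opposite sign. In the first reading 17 of 19 had a dye effect above 0, 9 of them past an adjusted p of 0.05 in limma, and the list was the only one of 31 called on the dye term (camera adjusted p = 2.7e-05, or 0.951 with an estimated correlation). The mean dye effect was 0.42, for Isg15 1.05. A dye bias of probes in general at this signal is argued against, since none of 10000 random lists matched on signal went beyond 0.27. Those lists leave out the correlation of genes within a list, so this comparison is generous. Microglia and macrophage markers had a mean dye effect of 0.18 ± 0.063 (SE over members), under that of the interferon list. That SE takes the members as independent, although their estimated correlation was 0.57. More microglia or macrophages in those mice therefore cannot be told apart by this test. A bias of the interferon probes alone, or a chance draw of mice with higher interferon genes into that dye, could each give the pattern and remain untested. Either would leave the cocaine term of the interferon list resting on how evenly 2 pairs per orientation balance.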
